A study of Mus musculus with 6 samples.

How the data were processed

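The data are bulk RNA-seq of MOC2, a mouse oral squamous cell carcinoma line, as parental cells and as cells with a knockout of p62, the autophagy receptor encoded by Sqstm1. The series design states 3 biological replicates per condition and that libraries of both groups were prepared in parallel. Per the labels' protocols, cells grew in serum-containing medium without added treatment. RNA was extracted with a column kit, poly(A) RNA was selected, and directional paired-end libraries were made. The labels do not say whether the knockout replicates came from a single clone, several clones or a pool. The p-values measure the spread between these cultures, and whether that includes a spread between independently made knockout lines is not known.

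Per the file headers, each deposited table lists total exon reads, unique exon reads, exon length and TPM per gene. The authors' counts are whole-number total exon reads per gene, not normalized, per the file headers. The authors' unique counts are whole numbers too and were used as an alternative. The deposited TPM values equal total exon reads divided by exon length and scaled to a fixed total, with a largest difference of 6.00e-11 on recomputation. The genome build is GRCm39 per the submitters' processing notes. The aligner, counter, annotation and strand setting are not given in the sources used here. Reads of overlapping or antisense genes could therefore not be told apart, and values of near-identical paralogs such as Ifit3 and Ifit3b are uncertain. The tables list 25526 genes. Of these, 3729 have an exon length of 0 and hold 0 reads.

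Libraries held between 32821860 and 41763980 exon reads. A count of 0 allows up to 3 reads, which was between 0.0718 and 0.0914 CPM per library. Wilson 95% intervals are given for shares of reads in single libraries, and these intervals and limits cover counting error only. Before averaging, libraries of a group were compared by a chi-square statistic over genes with a mean of at least 10 reads. Knockout replicates 1 and 3 were the closest pair, with 7.65 per degree of freedom, against 40.6 to 316 for the other pairs within a group. A value above the 1 of sampling noise argues only against repeated sequencing of the same library. It cannot show that the cultures were independent. All 6 libraries were counted as separate, following the stated design.

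Samples were grouped by the genotype label. The test was edgeR 4.0.16 quasi-likelihood (glmQLFit and glmQLFTest) under R 4.3.3, with filterByExpr, TMM factors, group as the only term and Benjamini-Hochberg adjustment over 12775 tested genes. A gene was called at an adjusted p below 0.05. CPM values are TMM-normalized unless stated otherwise, means are over 3 libraries with their SD, and the standard error of a log2 fold change was taken from the quasi-likelihood F statistic. Fold changes are knockout over parental.

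Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over 27 lists. The lists held 794 entries, of which 789 were found in the tables. They cover NRF2 targets, NF-kB targets, the type I interferon response, MHC class I presentation, autophagy, lysosomal genes, the ATF4 response, endoplasmic reticulum chaperones, glycolysis, hypoxia, cholesterol biosynthesis, oxidative phosphorylation, proteasome subunits, S phase, mitosis, p53 targets, epithelial genes, mesenchymal genes, collagens, chemokines and cytokines, YAP and TGF-beta targets, immediate early genes, leukocyte markers, endothelial markers, mitochondrially encoded transcripts, histones and ribosomal proteins. List scores per library are the mean log2 CPM of the members relative to the parental mean. A list member is counted as higher or lower by its edgeR adjusted p over all genes, and the count adjusted over the list alone is given beside it.

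Genes to name were set by a rule. It takes Sqstm1, then in each direction the 10 genes with the largest absolute log2 fold change among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a predicted gene, clone name or pseudogene. From each list it takes up to 2 called members with the largest positive and up to 2 with the largest negative log2 fold change, or the 1 member with the smallest p where none was called. Not every gene that this rule takes is reported here. The groups, the test, the lists, this rule and the alternatives were fixed before the data were examined, except where a choice is said to be later.

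The alternatives were RLE and upper quartile scaling, no filter on low counts (at least 1 read over the 6 libraries), a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the unique counts, the replicate number as a block, and leaving out each library in turn. For lists they also included camera with an estimated correlation and fry, which tests whether members move on balance in a single direction. On counts simulated for this comparison with 12775 genes, the edgeR test recovered 20 of 100 genes changed 2-fold and 84 of 100 changed 4-fold, with 5 false calls. DESeq2 recovered 49 and 91 of these, with 41 false calls. The simulation drew genes independently and held no library that stood apart from its group. These rates therefore need not hold for the measured libraries.

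GENCODE M21 on GRCm38 was used for the order of genes along chromosomes and for transcript GC content, matched by gene identifier for 12742 of the tested genes on the autosomes and X. No coordinates are given, since the deposited tables were made on another build.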

Results

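Gene expression was measured by RNA-seq in 3 parental and 3 p62 knockout cultures of MOC2, a mouse oral squamous cell carcinoma line. The comparison asked how the transcriptome differs between parental and p62-deficient cells. Parental replicates 1 to 3 held 39185828, 38490029 and 33349014 exon reads, and knockout replicates 1 to 3 held 32821860, 41763980 and 34301376. Between 14886 and 15460 genes had at least 1 read in a library.

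Sqstm1 (ENSMUSG00000015837), which encodes p62, was lower in all 3 knockout libraries, but by different amounts. It stood at 1567, 1783 and 2103 CPM in the parental libraries. In knockout replicates 1 and 3 it stood at 117 and 125 CPM, or 6.41% and 6.90% of the parental mean, and in knockout replicate 2 at 589 CPM, or 32.4%. Before scaling, the level in knockout replicate 2 was 575 CPM (Wilson 95% interval 568 to 582). The group means were 1818 ± 269 CPM for parental and 277 ± 270.1 CPM for knockout cells (SD, n = 3 each). The log2 fold change was -2.71 ± 0.65 (SE; edgeR adjusted p = 0.048). The adjusted p was 0.0502 with RLE scaling, 0.0547 with the stricter filter and 0.0959, 0.178, 0.136, 0.148 and 0.149 without parental replicates 1, 2 and 3 and knockout replicates 1 and 3. It was 0.000399 without knockout replicate 2, at a log2 fold change of -3.93.

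Knockout replicate 2 also stood apart across the transcriptome. The first principal component of log2 CPM held 60.9% of the variance and placed knockout replicates 1 and 3 at 60.5 and 61.3, knockout replicate 2 at -8.30 and the parental libraries between -43.7 and -31.5. The second component held 24.2% and placed knockout replicate 2 at 54.9, against 10.6, -17.3 and -34.5 for parental replicates 1 to 3. The Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.995 between knockout replicates 1 and 3. It was 0.951 between knockout replicates 1 and 2 and 0.972 between knockout replicate 2 and parental replicate 1.

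**Figure D1:**
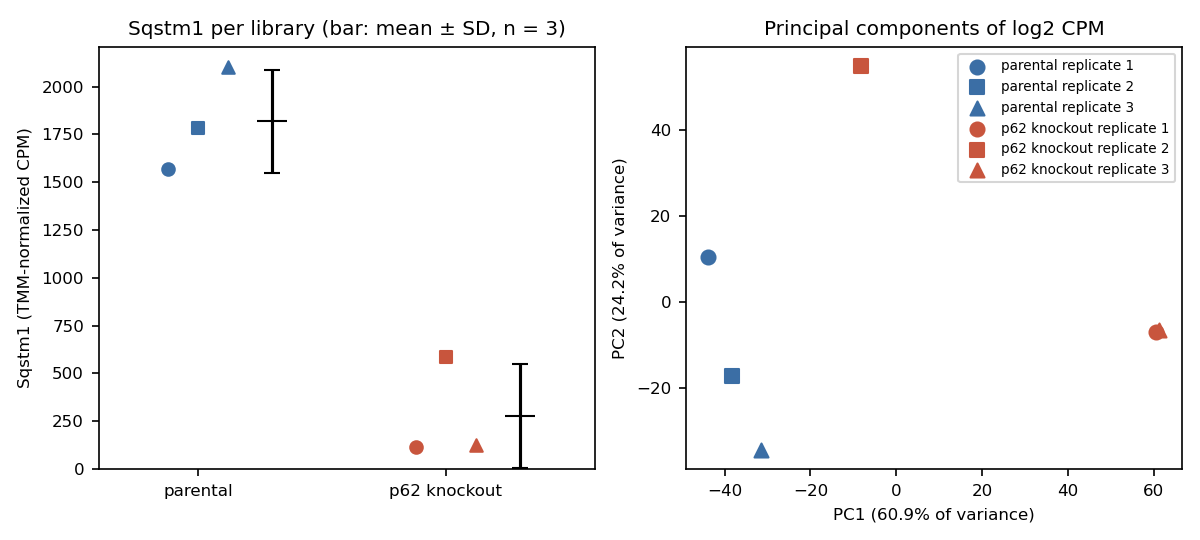
Left, Sqstm1 in TMM-normalized CPM for each library (points) with the group mean ± SD (n = 3); right, the 6 libraries on the first and second principal components of log2 CPM. Knockout replicate 2 holds 589 CPM of Sqstm1, against 117 and 125 in the other knockout libraries, and lies at -8.30 on the first component, between the parental libraries and the other knockout libraries.

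Of 12775 genes tested, 445 were higher and 715 lower in p62 knockout cells at an adjusted p below 0.05 (edgeR), of which 195 and 469 changed at least 2-fold. These counts changed strongly when single libraries were left out. Such fits have fewer than the 4 residual degrees of freedom of the full fit, so calls can be lost through lower power alone. In each of them, 0 of the 1160 called genes changed sign. Without knockout replicate 2, 2972 genes were higher and 3001 lower, and all 1160 genes called with 6 libraries were among them in the same direction. Without parental replicates 1 and 3 the counts were 125 and 278, and 5 and 101. Without knockout replicates 1 and 3 they were 1 and 38, and 1 and 29. Without parental replicate 2 the edgeR test called 0 genes, while 2494 had an unadjusted p below 0.05. Limma-voom called 0 and DESeq2 972 genes from those libraries, both run after seeing the edgeR count.

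The genes with the largest increases included several of DNA synthesis and chromatin. Hmgn2, which encodes a nucleosome-binding protein, rose from 23.3 ± 4.35 to 216 ± 159 CPM (log2 fold change 3.21 ± 0.76, SE; adjusted p = 0.046). Tyms, thymidylate synthase, rose 9.03-fold, Ccne2, cyclin E2, 7.93-fold and Hells, a chromatin remodeller of the SNF2 family, 5.31-fold. Tfrc, the transferrin receptor, rose 5.10-fold, from 80.1 ± 18.7 to 408 ± 220 CPM. Klk10 (8.90-fold), a secreted kallikrein-family protein, Inpp4b (7.99-fold), a phosphoinositide phosphatase, Mns1 (7.92-fold), Cars2 (5.90-fold), the mitochondrial cysteinyl-tRNA synthetase, and Edn1 (5.57-fold), endothelin 1, completed this group. The rule for naming these genes required that the groups not overlap, yet knockout replicate 2 was often close to the parental range. Hmgn2 stood at 302, 32.8 and 314 CPM in knockout replicates 1 to 3. Edn1 was more even, at 15.1, 9.68 and 13.4 CPM against at most 2.47 CPM in parental cells. With limma-voom, the calls of Hmgn2, Tyms, Klk10, Inpp4b, Ccne2, Mns1 and Hells were lost. The call of Hmgn2 was lost in 8 of the other settings, among them the stricter filter and the replicate block.

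The genes with the largest decreases were led by Cck, which encodes the peptide hormone cholecystokinin. It fell from 15.5 ± 3.15 to 0.474 ± 0.326 CPM (log2 fold change -5.05 ± 0.59, SE; adjusted p = 0.00934). Of the other 9, Ifit3, Ifi44, Irf7, Ifit3b and Oas3 are interferon-induced genes and were between 9.78-fold and 24.5-fold lower. Lilrb4b (17.7-fold lower), a leukocyte immunoglobulin-like receptor, was at 50.7, 15.9 and 14.6 CPM in parental cells and at 3.01 CPM or less in knockout cells. Aebp1, linked to collagen fibres, was 10.2-fold lower, Aldh1a3, a retinaldehyde dehydrogenase, 8.73-fold lower and Il11, a cytokine of the IL-6 family, 7.71-fold lower. Aldh1a3 stood at 22.4, 15.4 and 20.5 CPM in the knockout libraries against 170 ± 53.5 CPM in parental cells. Calls for all 20 genes were lost without parental replicate 2, and those for Edn1, Ifit3, Irf7, Aebp1 and Aldh1a3 held in every other setting run.

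**Figure D2:**
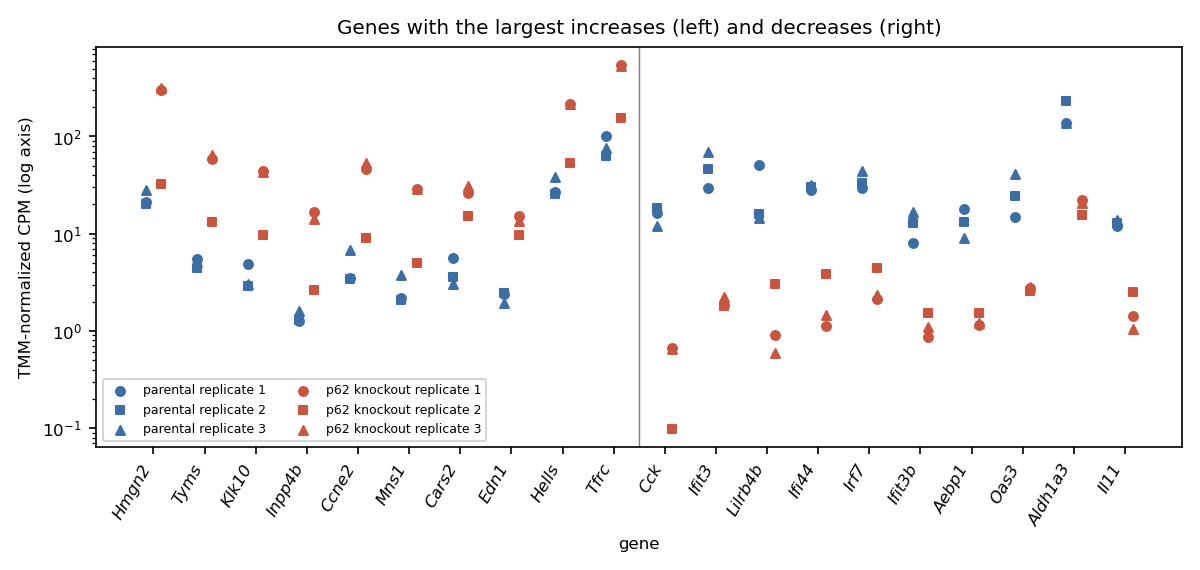
TMM-normalized CPM on a log axis for the 10 genes with the largest increases (left) and the 10 with the largest decreases (right), one point per library. For genes that rose, such as Hmgn2 at 302, 32.8 and 314 CPM, knockout replicate 2 lies below the other knockout libraries, while for Ifit3 the 3 knockout libraries lie at 1.83, 1.81 and 2.23 CPM.

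Genes of the type I interferon response fell as a group and by similar amounts in each knockout library. Of 34 members tested, 29 were lower, 0 were higher and 5 did not pass; adjusted over the list alone, 33 were lower. The median log2 fold change was -1.96, or 3.88-fold lower, and all 34 had a negative sign. Ifit3, an antiviral RNA-binding protein, fell from 48.1 ± 19.6 to 1.96 ± 0.233 CPM (SD, n = 3). Ifi44 fell 13.8-fold, and Irf7, a transcription factor of interferon genes, from 35.6 ± 7.64 to 2.96 ± 1.26 CPM. The list score was -2.23, -2.14 and -2.14 in knockout replicates 1 to 3, against a parental SD of 0.278. The list was lower by camera (adjusted p = 1.86e-24), and adjusted p = 0.486 with an estimated correlation. By fry it was also called lower (adjusted p = 0.0034). The direction was negative for all tested members in each set of 5 libraries. The number called lower was 25, 0 and 14 without parental replicates 1 to 3 and 9, 33 and 7 without knockout replicates 1 to 3.

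Of 18 MHC class I presentation genes, 7 were lower, 0 higher and 11 did not pass, and 7 of the 18 had a positive sign. Adjusted over the list alone, 8 were lower and 2 higher. H2-T23, a non-classical class I molecule, fell 4.32-fold and Tap1, a subunit of the peptide transporter, 3.28-fold. The camera test gave adjusted p = 0.0148, and adjusted p = 0.526 with an estimated correlation. It was 0.0820 without knockout replicate 2, where 9 members were lower and 2 higher.

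Chemokines, cytokines and checkpoint ligands moved both ways. Of 39 tested, 5 were higher, 8 lower and 26 did not pass; adjusted over the list alone the counts were 5 and 10. Cxcl5, a neutrophil-attracting chemokine, rose 2.81-fold (adjusted p = 0.04996, lost in 9 of the other settings), with 312, 117 and 292 CPM in knockout replicates 1 to 3. Cxcl14 rose 3.76-fold but stayed at 0.960 ± 0.228 CPM (lost in 7 of the other settings). Il11 and Ccl5, a T cell-attracting chemokine, fell, Ccl5 by 4.81-fold to 1.99 ± 0.576 CPM. Their calls were lost in 3 and 7 of the other settings, that of Ccl5 also with limma-voom. On balance the list was lower (camera adjusted p = 0.0167), and adjusted p = 0.526 with an estimated correlation; without knockout replicate 2 it was 0.161, with 6 members higher and 14 lower. NF-kB targets split evenly, with 4 higher, 4 lower and 19 not passing of 27, and 4 and 7 adjusted over the list alone (camera adjusted p = 0.366); leaving out knockout replicate 2 gave 6 higher and 9 lower. Cxcl1 rose 2.36-fold, a call lost in 8 of the other settings. Ptgs2, the inducible cyclooxygenase, fell 2.74-fold from 778 ± 105 to 284 ± 109 CPM, a call lost in 6.

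Immediate early genes were lower, with 5 of 28 lower, 0 higher and 23 not passing; adjusted over the list alone, 11 were lower. Egr1, a growth factor-induced transcription factor, fell 4.54-fold, with 11.4, 34.0 and 10.1 CPM in knockout replicates 1 to 3 against 84.1 ± 15.5 CPM in parental cells, and Egr3 fell 3.69-fold. The camera test gave adjusted p = 5.84e-05, and adjusted p = 0.534 with an estimated correlation. The count was 19 lower and 1 higher without knockout replicate 2, and 0 without knockout replicate 1 or 3. Of 23 YAP and TGF-beta early targets, 0 were called by edgeR over all genes or over the list alone. The smallest p belonged to Tgfbr1, at 46.3 ± 4.42 and 65.4 ± 4.58 CPM (adjusted p = 0.062). With knockout replicate 2 left out, 4 members were higher and 9 lower. Camera gave adjusted p = 0.272 for this list, while fry called it lower (adjusted p = 0.0296).

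Genes of the antioxidant response, autophagy and the lysosome were examined because p62 is known to act there. NRF2 is a transcription factor of the antioxidant response whose inhibitor KEAP1 is bound by p62. Of 28 NRF2 targets, 0 were higher, 5 lower and 23 did not pass by edgeR, and 4 were higher and 6 lower adjusted over the list alone (camera adjusted p = 0.505); leaving out knockout replicate 2 gave 9 higher and 9 lower of 29, and DESeq2 5 and 6 of 32. Blvrb, biliverdin reductase B, and Mgst1, a microsomal glutathione transferase, fell 2.55-fold and 2.54-fold, Blvrb to 8.39 ± 0.209 CPM in knockout cells. Autophagy genes had 2 of 40 lower, 0 higher and 38 not passing, and 0 called adjusted over the list alone. These were Map1lc3a, an LC3 protein of the autophagosome membrane, which fell 1.75-fold, and Vmp1, a membrane protein of autophagosome formation, 1.46-fold. The list was lower by camera (adjusted p = 0.0194), and adjusted p = 0.824 with an estimated correlation; the call was lost without parental replicate 3, knockout replicate 1 or knockout replicate 3, with an adjusted p of up to 0.102. The list score was -0.397, -0.001 and -0.406 in knockout replicates 1 to 3. In the fit without knockout replicate 2, 21 autophagy genes were lower and 1 higher, and the list's adjusted p was 0.000659. Lysosomal genes had 7 of 32 lower, 0 higher and 25 not passing, and 10 lower and 1 higher adjusted over the list alone. Naglu and Gaa, both lysosomal glycosidases, fell 2.40-fold and 2.27-fold. The list was lower by camera (adjusted p = 0.00399), and adjusted p = 0.526 with an estimated correlation. With knockout replicate 2 left out, 16 lysosomal genes were lower and 2 higher.

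Endoplasmic reticulum chaperones and related genes had 4 of 19 higher, 0 lower and 15 not passing, and 5 higher adjusted over the list alone. Selenos and Sec61b, of the degradation and translocation machinery, rose 2.02-fold and 2.01-fold. The camera test gave adjusted p = 0.0253, and adjusted p = 0.824 with an estimated correlation. The list score was 0.874 in knockout replicate 2 and 0.076 and 0.093 in replicates 1 and 3, and the adjusted p was 0.795 without knockout replicate 2, where 5 members were higher and 3 lower. The call was also lost without parental replicate 2 and with fry. Of 30 genes of the ATF4 amino acid response, 0 were called by edgeR over all genes or the list alone (camera adjusted p = 0.275). Nupr1, a stress-induced chromatin protein, had the smallest p, at 387 ± 122 and 156 ± 60.4 CPM (adjusted p = 0.052). Without knockout replicate 2, 16 members of this list were lower and its adjusted p was 0.00289.

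The scores of the S phase and mitosis lists were above the parental range in knockout replicates 1 and 3, though most members did not pass. In knockout replicate 2 both scores were within that range. The S phase score was 1.84, 0.212 and 1.89 in knockout replicates 1 to 3, and -0.468, -0.050 and 0.518 in the parental libraries. Of 38 genes of S phase and DNA replication, 8 were higher, 0 lower and 30 did not pass, and 24 were higher adjusted over the list alone. The count of 8 by edgeR was 2 with limma-voom, where Tyms and Ccne2 lost their call, 25 with DESeq2 and 0 to 1 without any library but knockout replicate 2. Tyms stood at 58.5, 13.2 and 63.8 CPM and Ccne2 at 46.5, 9.12 and 52.9 CPM in knockout replicates 1 to 3, against 4.99 ± 0.492 and 4.57 ± 1.92 CPM in parental cells. The list was higher by camera (adjusted p = 2.38e-08), and adjusted p = 0.653 with an estimated correlation. The list call was lost with fry (adjusted p = 0.166). In the fit without knockout replicate 2, 36 members were higher. Of 35 mitosis genes, 0 were higher, 1 was lower and 34 did not pass, with the same counts over the list alone. The lower gene was Pttg1, securin, which fell 1.92-fold. The list score was 2.44, -0.716 and 2.45 in the knockout libraries and -1.35, 0.293 and 1.06 in the parental libraries. The list was higher by camera (adjusted p = 0.00384), and adjusted p = 0.824 with an estimated correlation; it was 0.154 without parental replicate 1. Leaving out knockout replicate 2, 24 mitosis genes were higher and 1 lower. Of 5 replication-dependent histone genes tested, 1 was higher, H2bc4 (3.10-fold), also adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.526 with an estimated correlation). The histone score in knockout replicate 2 was 0.464, above the parental maximum of 0.170. The fit without knockout replicate 2 tested 10 histone genes and called 6 higher. Of 29 p53 targets, 1 was lower and 0 higher over all genes, and 0 adjusted over the list alone (camera adjusted p = 0.273); leaving out knockout replicate 2 gave 3 higher and 10 lower. This was Gadd45a, a stress-induced growth arrest gene, which fell 4.02-fold to 30.5, 93.8 and 34.3 CPM.

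Scores of the cholesterol, proteasome and oxidative phosphorylation lists were above the parental range in knockout replicates 1 and 3. In knockout replicate 2 they were below it, at -0.501, -0.110 and -0.146 against parental minima of -0.209, -0.072 and -0.088. Of 24 genes of cholesterol biosynthesis, 0 were called by edgeR over all genes or the list alone, and 9 higher by DESeq2. The list score was 1.30, -0.501 and 1.30 in knockout replicates 1 to 3, and without knockout replicate 2 21 members were higher. The list was higher by camera (adjusted p = 0.00591), and adjusted p = 0.824 with an estimated correlation. Proteasome subunits had 1 of 32 higher, Psmd6 (2.04-fold, adjusted p = 0.04997, lost in 9 of the other settings), 31 not passing, and 0 adjusted over the list alone (camera adjusted p = 0.00444, and adjusted p = 0.824 with an estimated correlation). Of 39 nuclear-encoded genes of oxidative phosphorylation, 0 were called by edgeR over all genes or the list alone, and 5 higher by DESeq2 (camera adjusted p = 0.0148, and adjusted p = 0.824 with an estimated correlation). Ndufs1, of complex I, had the smallest p, at 75.1 ± 11.5 and 112 ± 20.3 CPM (adjusted p = 0.087). The list call was lost with fry and without parental replicate 2 or knockout replicate 3, with camera at an adjusted p of up to 0.197. Without knockout replicate 2, 24 proteasome and 18 oxidative phosphorylation genes were higher.

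Of 18 glycolysis genes, 0 were higher, 3 lower and 15 did not pass, and 2 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.617). With knockout replicate 2 left out, the balance turned to 8 higher and 4 lower, and DESeq2 gave 5 higher and 4 lower. Eno2, the neuronal enolase, fell 5.20-fold and Pfkm, the muscle phosphofructokinase, 1.70-fold. Of 17 hypoxia genes, 1 was higher, Egln1 (1.73-fold, adjusted p = 0.04996, lost in 9 of the other settings), and 2 were lower, P4ha2 (1.59-fold) and Mxi1 (1.57-fold), also adjusted over the list alone (camera adjusted p = 0.688); leaving out knockout replicate 2 gave 4 and 3. Of 13 mitochondrially encoded transcripts, 2 were higher, mt-Nd2 (2.29-fold) and mt-Nd1 (2.20-fold), and 3 adjusted over the list alone (camera adjusted p = 0.193); leaving out knockout replicate 2 gave 3 higher and 2 lower. The list was called higher by camera without knockout replicate 1 (adjusted p = 0.00832). These transcripts together took 1.56%, 1.36% and 1.73% of reads in parental replicates 1 to 3 and 0.952%, 1.78% and 1.36% in knockout replicates 1 to 3. The Wilson 95% interval of the lowest share was 0.948% to 0.955%. Of 40 cytoplasmic ribosomal protein genes, 0 were called by edgeR over all genes or the list alone (camera adjusted p = 0.617). Rps25 had the smallest p, at 490.3 ± 72.2 and 679 ± 163 CPM (adjusted p = 0.168). In the fit without knockout replicate 2, 15 of these genes were lower and the list was called lower by camera (adjusted p = 0.00323).

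The scores of the collagen and mesenchymal lists were below the parental range in each knockout library, though most members did not pass. Of 15 collagen and fibroblast genes tested, 4 were lower, 0 higher and 11 did not pass, and 9 were lower and 2 higher adjusted over the list alone. Col3a1 fell 5.19-fold to 1.24 ± 0.293 CPM and Fstl1, a secreted glycoprotein, 4.95-fold to 6.78 ± 3.13 CPM. The list score was -0.791, -1.43 and -0.789 in knockout replicates 1 to 3, against a parental SD of 0.190 (camera adjusted p = 0.00315, and adjusted p = 0.534 with an estimated correlation). The fit without knockout replicate 2 gave 10 lower and 1 higher of 17. Of 31 mesenchymal transition genes, 7 were lower, 0 higher and 24 did not pass, and 11 were lower and 1 higher adjusted over the list alone; 11 of the 31 had a positive sign. The matrix metalloproteinases Mmp9 and Mmp10 fell 9.24-fold and 4.46-fold, to 0.795 ± 0.264 and 1.87 ± 0.371 CPM. The camera test gave adjusted p = 0.00384, and adjusted p = 0.526 with an estimated correlation; it was 0.0860 without knockout replicate 2, where 10 members were lower and 4 higher of 32. Of 36 epithelial and keratinocyte genes, 3 were higher, 1 lower and 32 did not pass, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.617). The fit without knockout replicate 2 gave 14 higher and 9 lower of 37. Krt8, a keratin of simple epithelia, rose 2.53-fold (lost in 8 of the other settings) with 1801, 840 and 1887 CPM in knockout replicates 1 to 3. The desmosomal cadherin Dsg3 rose 3.34-fold but stayed at 0.391 ± 0.055 CPM (also lost in 8), and Itga6, an integrin of basal cells, fell 1.54-fold.

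Markers of other cell types were mostly below the filter on low counts. Of 25 macrophage and leukocyte markers, 4 were tested and 1 was lower, also adjusted over the list alone. This was Cd68, a lysosomal glycoprotein, which fell 5.67-fold from 19.8 ± 2.08 to 3.48 ± 0.774 CPM. The median log2 fold change of this list was 0.39 and its mean -0.25, and camera gave the direction of the mean (adjusted p = 0.566). Of 15 endothelial markers, 4 were tested, 0 were called over all genes and 1 was lower adjusted over the list alone (camera adjusted p = 0.0462, and adjusted p = 0.526 with an estimated correlation). Plvap had the smallest p, at 0.971 ± 0.180 and 0.436 ± 0.089 CPM (adjusted p = 0.075). The list's call was lost without parental replicates 1 or 2 or knockout replicate 2, with an adjusted p of up to 0.263, and with upper quartile scaling and both other filters.

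**Figure D3:**
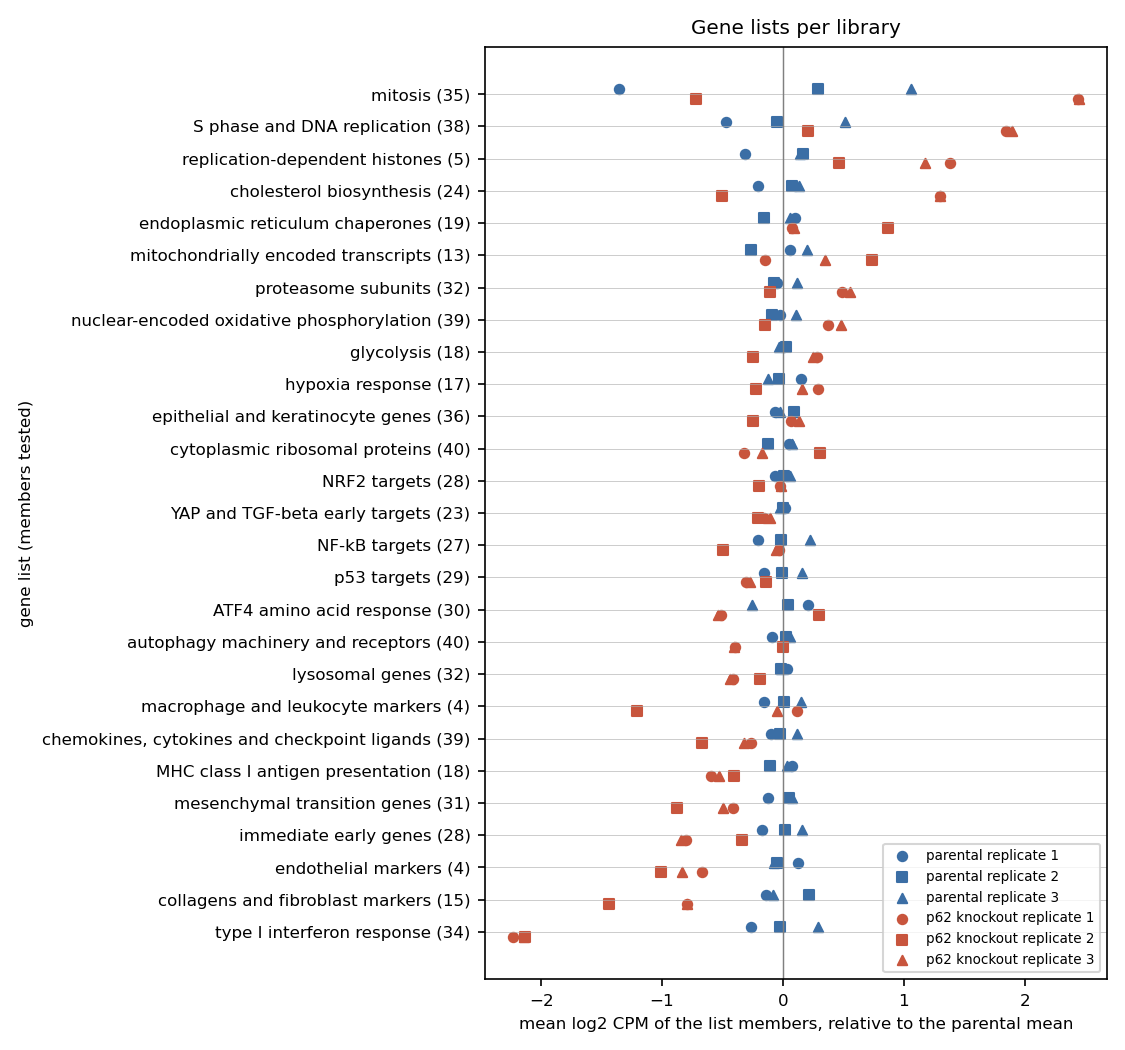
Mean log2 CPM of each gene list relative to the parental mean (x axis), one point per library and 27 lists ordered by the knockout mean, with the number of members tested in brackets. The interferon list lies at -2.23, -2.14 and -2.14 in the knockout libraries, while the mitosis list lies at 2.44 and 2.45 in knockout replicates 1 and 3 and at -0.716 in knockout replicate 2.

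Taking lists as a whole, 7 were higher and 9 lower in knockout cells by camera at an adjusted p below 0.05. With an estimated correlation 0 of these 16 calls held, the smallest adjusted p being 0.486 for the interferon list. By fry, 9 lists were called, 1 higher and 8 lower. The higher list was that of the histones. The lower ones were the interferon, MHC class I, lysosomal, mesenchymal, collagen, chemokine, YAP and endothelial lists. In splits of the libraries that mixed the groups, camera with the preset correlation called between 8 and 16 lists. Each of these splits still held part of the difference between the genotypes, so they cannot show how often camera calls lists in its absence. The number of camera calls alone did not set the real grouping, with 16, apart from these. Outside the interferon list, the edgeR fits without knockout replicate 1 or 3 called at most 1 member of any list, and the fit without parental replicate 3 at most 2.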

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

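The directions of the named genes did not reverse in any setting run. RLE and upper quartile scaling, no filter, limma-voom and the unique reads kept the gene counts within 1.5 times of the reported ones. The stricter filter left 114 genes higher and 285 lower by at least 2-fold. It tested fewer genes (10286), but genes that it still tested, such as Krt8 and Cxcl5, also lost their call. The cause was not tested. DESeq2 called 1399 genes higher and 1353 lower, with 518 higher by at least 2-fold; the cause was not tested. Leaving out 1 library gave 0 to 2972 genes higher and 0 to 3001 lower, and 0 to 1066 and 0 to 1224 by at least 2-fold. The log2 fold change of Sqstm1 ran from -3.93 to -2.32 over these fits, and was -2.70 with RLE scaling and -2.72 with the stricter filter, both past the adjusted p limit by little. With the replicate number as a block, 54 genes were higher and 203 lower, and 51 and 201 by at least 2-fold. Deviations from the group means correlated at -0.366, -0.105 and 0.284 for replicates 1 to 3 across genes. With parental replicate 1, knockout replicates 1 to 3 gave -0.366, 0.391 and -0.331. The knockout deviations thus mostly set replicate 2 against the others, so these values cannot tell whether the numbers pair the libraries. The block ended no list call.

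Of the other 62 named genes, RLE scaling and the unique reads left all 62 on their side of the limit, and upper quartile scaling 57, no filter 58, DESeq2 57, limma-voom 48 and the block 37. The stricter filter ended 6 of their calls. Without parental replicates 1 to 3, 29, 6 and 21 stayed, and without knockout replicates 1 to 3, 16, 58 and 14.

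With an estimated correlation camera called 0 lists higher and 0 lower, and fry called 1 higher; the cause was not tested. Among others, fry ended the calls of the autophagy, cholesterol, proteasome, mitosis and immediate early lists, and the stricter filter that of the histones. Without a filter on low counts 3 named genes lost their call, Dsg3, Cxcl14 and Vmp1; the cause was not tested. At this depth a gene such as Dsg3, at 0.391 CPM in knockout cells, was measured from few reads.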

Other observations

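The genes of the interferon pathway in the next paragraph were chosen after the interferon list had been seen. The tests of parental RNA mixed into knockout replicate 2, of leukocytes, of growth state for the interferon genes and of fewer copies as the reason for lower genes on the chromosome of Sqstm1 were also chosen only after the result was seen.

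The components upstream of interferon-induced genes differed in how they moved. The transcription factors Stat2 and Irf9, themselves interferon-induced, fell 2.87-fold and 3.76-fold (edgeR adjusted p = 0.019 for both), and the RNA sensors Rigi and Ifih1 fell 2.99-fold and 2.57-fold. Stat2, Irf9, Rigi and Ifih1 are all members of the interferon list, so their fall repeats the result of that list. Irf3, Mavs, Tbk1, Cgas, Jak1 and Ifnar1 did not pass the test, with log2 fold changes between -0.16 and 0.34. The same held for Irf1 and Socs1, at -0.32 and 0.39. Tlr3 and Tyk2 did not pass either, at log2 fold changes of 0.87 and -0.65 (adjusted p = 0.0598 and 0.0737), but passed without knockout replicate 2 (0.00158 and 0.0120). The receptor chain Ifnar2 fell 1.59-fold, from 29.6 ± 0.435 to 18.6 ± 1.77 CPM (SD, n = 3; adjusted p = 0.036). Sting1 stood at 19.7 ± 8.23 and 8.64 ± 3.75 CPM and did not pass (adjusted p = 0.122). Ifnb1 had 2 reads in parental replicate 3 and 0 in the other 5 libraries, and Ifna2 and Ifna4 had 0 reads in all 6, which allows up to 0.0914 CPM in the shallowest library. A difference in Ifnb1, Ifna2 or Ifna4 was not detectable at this depth, and not every interferon gene was examined.

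For the interferon genes, 3 technical explanations were weighed. Leukocytes in the parental cultures would bring their abundant transcripts, but Ptprc, Lyz2, Tyrobp, Fcer1g and Laptm5 summed to at most 0.102 CPM in a parental library. At equal mitosis score the log2 interferon score of the knockout libraries still differed by -2.25 (SE 0.192, 6 libraries). Growth state, as far as the mitosis score reads it, therefore does not account for the difference. Other aspects of the culture state were not tested. The 31 interferon genes on other chromosomes than that of Sqstm1 had a median log2 fold change of -1.92. Fewer copies of that chromosome would not lower these genes directly, and an indirect effect was not tested. What stays open is whether the fall of the interferon genes follows from the absence of p62 or from a property of the knockout line. The labels do not tell clones apart.

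For knockout replicate 2, parental RNA mixed into the library was tested through the share that each gene would need. Genes at least 4-fold lower in the other knockout libraries gave a median share of 0.168 (60 genes) and genes at least 4-fold higher 1.02 (143 genes), a difference of 0.850 that no single share can give. For Sqstm1 alone the share was 0.276, but interferon genes gave 0.0469 (bootstrap 95% interval over genes -0.00705 to 0.0900, 13 genes). This argues against parental RNA as the source of the Sqstm1 in that library. Slower growth of the culture of knockout replicate 2 was weighed through its likeness to a parental library. Across tested genes, its difference from the other knockout libraries correlated with parental replicate 1 minus replicate 3 at r = 0.377 (Spearman 0.256), where genes are not independent. These parental libraries were picked after their mitosis scores of -1.35 and 1.06 had been seen. Growth was not measured, and r cannot tell slower growth from another trait shared by parental replicate 1 and knockout replicate 2. Slower growth is left open. A different knockout clone in that culture was not tested.

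Genes on the chromosome that carries Sqstm1 were lower in each knockout library. Relative to all genes, the median log2 fold change of its 1073 tested genes was -0.199 (bootstrap 95% interval -0.235 to -0.163), against -0.078 to 0.075 on the other chromosomes, and it was -0.198, -0.213 and -0.195 in knockout replicates 1 to 3. Removing the trend with GC content left -0.181 (-0.210 to -0.140), which argues against that trend as the whole cause. Both intervals are over genes, which are not independent, and do not measure the spread between cultures. Over the genome, 0 of 100 random gene orders reached the spread of means over windows of 50 neighbouring genes (SD 0.155, highest random 0.121), which is consistent with copy number differences but also with shared regulation of neighbours. On this chromosome all 21 windows lay below 0, which no other chromosome showed, and 109 genes were called lower against 10 higher. A shift along the whole chromosome is what fewer copies would show, and separate groups of regulated neighbours would not need it. The loss of 1 of 4 copies in all cells would give -0.42, which the median did not reach. The copy number was not measured and the explanation was weighed after the shift was seen, so fewer copies, possibly in some of the cells, stay open beside regulation.

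Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 1160 called genes and 664 by at least 2-fold, the highest other split 0 and 0, so 1 of 10 splits reached each count. For gene lists the real split called 16 and the highest other split also 16, so 2 of 10 reached that count. The lowest other split still called 8 lists, so camera with the preset correlation called lists under every grouping of the libraries. Every other split still held part of the difference between the genotypes. The Spearman correlation across genes of log2 fold change with exon length was -0.149, between the limits set in advance for and against a length bias, which is left open.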
